A study of Mus musculus with 4 samples.

How the data were processed

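Total RNA from ureters of NMRI mouse embryos at embryonic day 18.5 was compared on 4 arrays of 2 colours, each carrying RNA of a conditional mutant in 1 channel and RNA of a control in the other. The mutant, called cKO here, was Pax2-cre/+ with both Trp63 alleles floxed for the ΔN form of p63, the transcription factor of basal epithelial cells. The control carried at least 1 floxed allele, and the labels list no cre for it. Per the labels, 200 ng of total RNA went into 1 round of amplification with aminoallyl nucleotides, and the cRNA was coupled to AlexaFluor555 (green channel) or AlexaFluor647 (red channel). The cKO was red on arrays 1 and 3 and green on arrays 2 and 4, so the dyes were balanced against the genotype. The labels give array 2 as a male pair and the other 3 arrays as female pairs. All 4 arrays lay on 1 slide and were scanned together, so no slide or scan effect could be separated. Nothing in the labels says whether each RNA came from a separate embryo or from several, so p-values measure the spread between these arrays only, within a dye orientation.

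The deposited scanner files hold spot intensities on a linear scale (mean signal and median local background of each channel, and Agilent's processed signals), read from the images by the authors with Agilent Feature Extraction 10.7.3.1, per the file headers and the submitters' processing notes. They also hold a deposited log10 ratio of red over green per spot. The deposited value table holds log2 ratios of cKO over control, centred at a median of 0.00 on each array. Its scale and direction were found by setting each column against the scanner values of the same array, where the slope on the turned log2 ratio of the brighter probes lay between 0.999 and 1.00. Between 7718 and 12487 probes per array have a value of exactly 0 in it, and over 99.9% of these were among the dimmer probes. How the authors handled dim probes to obtain those zeros is not given in the sources used here.

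Each array held 39429 probes with 4 spots per probe. Probe names were updated through a table of RefSeq genes (GRCm38.p6, used for names only): 28328 probes matched by accession, 3400 by symbol and 243 by an older symbol, 1777 kept the name in the files, and 5681 had no gene name. Probe positions are those of the files, in mm9. Mean signals were corrected against the local background with normexp (offset 50), normalized within each array by loess with control spots at weight 0, and turned to log2 of cKO over control. Spots with an outlier flag (3.04% to 3.58% per array) were left out, and the remaining spots of a probe were averaged. No spot was saturated. A gene was tested if at least 1 of its probes was well above background in most of its spots on all 4 arrays in the channels of at least 1 genotype, which left 18161 genes. The probe with the highest mean signal stood for the gene. Among the 5506 genes with several passing probes, 0 had probes past the threshold in opposite directions.

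Ratios were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with the dye as a term, which leaves 2 residual degrees of freedom beside the prior. P-values were adjusted by Benjamini-Hochberg over all genes, and the threshold was an adjusted p of 0.05. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the 26 lists, or over the 3 lists of hepatocyte, adrenal cortex and intestinal epithelium genes among themselves. With an estimated correlation, camera rests on the 2 residual degrees of freedom. Where a genotype was well above background on at most 1 array, the fold is given as a lower limit against the lowest level that passed on each array. Level errors are SDs of the log2 ratio over 4 arrays, and the number of arrays limits the precision. These SDs include the difference between the dye orientations. The p-values do not, since they rest on the spread within an orientation and on the prior. For a gene list the median is that of the members' fitted ratios, and the error is the SD of the 4 per-array medians. The mean of the per-array medians can differ from the median given. The difference between the male pair and the female pairs was a further coefficient in the same model, with 1 residual degree of freedom; beside the dye term it equals array 2 minus array 4. Pairing by array is built into the ratios; fits of the separate channels were run as alternatives, with the array as a random block (intra-spot correlation 0.907, statmod 1.5.0) and without it.

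The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule took Trp63, the 12 largest rises and the 12 largest falls among genes past the threshold with the same sign on 4 arrays and a standard symbol, and from each list up to 4 members past the threshold with the lowest p, or the 2 brightest members where none passed. It gave 95 genes, not all of which are named in the text. The other genes named were chosen after their values were seen, to complete small counts or as known markers: Cyp2f2, Dsc3, Itga6, Cd44, Dsp, Upk1a, Upk1b, Upk2, Upk3a, Vgll1, Krt8, Cdh1, Acta2, Myh11, Tbx18, Lor, Krt4, Muc20, Lgr5, Tff3, Axin2, Stra6, Gli1, Hhip, Trf, and the hepatocyte, intestinal and adrenal genes outside the rule. Also chosen after the values were seen were Prm2, Prm3, Tnp1 and Tnp2, to check for germ cell RNA, and the kidney genes Lrp2 and Slc34a1. Xist and the Y-linked genes served to check the sex labels. The lists of hepatocyte, adrenal cortex and intestinal epithelium markers were written after the main values were seen.

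The same functions were tested on simulated arrays with the levels and dye effects of the 18161 genes and a spread drawn from the fitted prior, 200 of them changed. The cKO against control fit recovered 60% of the genes changed by 0.5 on the log2 scale, 98% of those changed by 1, and 100% of those changed by 1.5 and by 2. It called 5 unchanged genes. Camera at the preset correlation called a list of genes all lowered by 1 and did not call a random list. The simulated genes varied independently, so this does not check the preset correlation where members vary together. In the data the estimated correlation of the superficial urothelium list was 0.83. The alternatives covered the background correction, the normalization within and between arrays, the filter, the dye term, the rules for probes and spots, the variance model, array weights, the deposited value table, the thresholds and leaving out each array. The 17214 negative-control spots per array were used in the background fit only.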

Results

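The series compares the ureters of embryos in which ΔNp63 was to be removed by Pax2-cre with those of control embryos of the same stage, and asks which transcripts differ in the ureter just before birth. The data are 4 arrays with 8 RNAs, 4 from cKO and 4 from control ureters, in 3 female pairs and 1 male pair. Median mean signals per channel lay between 460.3 and 607.3 units against median backgrounds of 31 to 82. On array 1, 90.0% of the green spots and 82.6% of the red spots were well above background, against 75.0% to 76.5% and 72.4% to 72.9% on the other arrays. Log2 ratios of the 18161 tested genes correlated between arrays at r = 0.53 to 0.73, a correlation across genes, which are not independent replicates. The sign was the same on 4 arrays for 30.6% of the genes, where chance gives 12.5%.

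Trp63, the targeted gene, fell 4.52-fold in the cKO, with a log2 ratio of -2.18 ± 0.50 (SD, n = 4; limma adjusted p = 0.00207). The ratio was -2.86, -1.68, -2.03 and -2.13 on arrays 1 to 4. This value comes from the brightest of 4 Trp63 probes, at chromosome 16, 25892012 to 25892071 (mm9). The probes at 25867718 to 25867777 and at 25821344 to 25821403 fell by 1.44 and by 1.77. The probe at 25871159 to 25871218 had a ratio of -0.14 ± 0.10 (adjusted p over probes 0.280). Averaged over the 4 probes, the Trp63 ratio was -1.38 in place of -2.18, and the adjusted p ranged from 2.43e-06 to 0.00954 over the alternatives. The files do not place the floxed exon, and a probe outside the deleted part does not check the deletion itself.

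**Figure D1:**
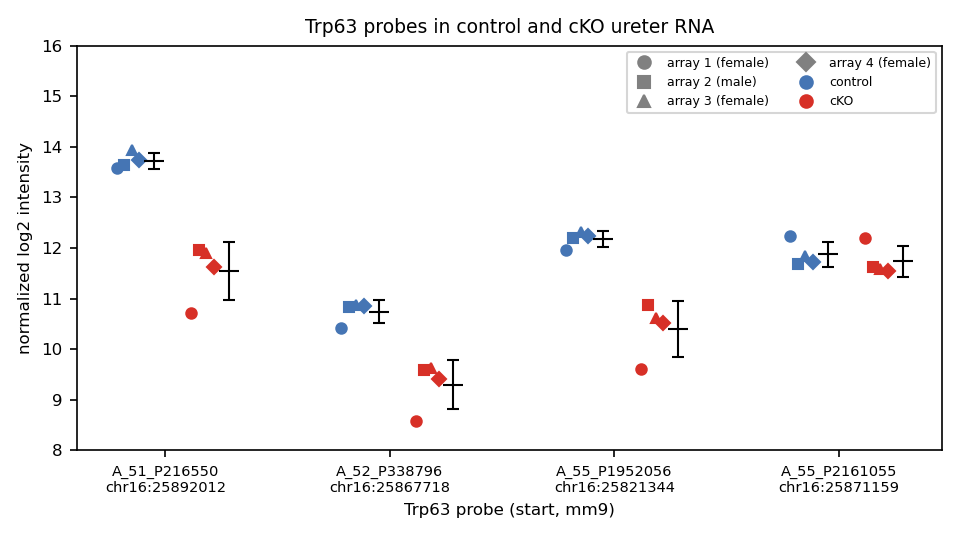
Normalized log2 intensity (vertical axis) of the 4 Trp63 probes in control (blue) and cKO (red) RNA, with a symbol per array and bars for the mean and SD of 4 arrays. At the 4 probes the cKO lies below the control on each array, with mean ratios of -2.18, -1.44 and -1.77 and, at the probe starting at 25871159, of -0.14.

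Krt5, Krt15 and Pkp1 were among the genes that fell most in the cKO ureters, and Prm1, gasdermin C genes, Msln and Spp1 among those that rose most. At the threshold, 530 genes were higher and 1023 were lower in the cKO at an adjusted p under 0.05 (limma). Of these, 527 and 1018 had the same sign on 4 arrays. At an unadjusted p under 0.05 there were 1969 and 2329. By size alone, 89 genes were at least 2-fold higher on average and higher on each array, and 201 were at least 2-fold lower and lower on each array; these counts were 166 and 307 with Agilent's processed signals and 133 and 259 with the deposited value table. With an array left out the counts were 277 to 359 higher and 554 to 768 lower; they were 277 and 584 without array 1, 287 and 709 without array 3, and 297 and 554 without array 4. With the array as a random block in a fit of the separate channels, 1472 genes were higher and 1899 were lower, and without the block 37 and 193.

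Keratin genes of basal cells were among the 12 largest falls. Keratin 5, the classical basal cell keratin, fell 7.26-fold (Krt5, -2.86 ± 0.10), and its basal partner Krt15 fell 5.86-fold (-2.55 ± 0.13, adjusted p = 0.000155 for both). Dnmt3l, a cofactor of DNA methyltransferases, fell 7.3-fold (-2.87 ± 0.07), Ly6d 7.2-fold (-2.85 ± 0.19) and Mir205hg, the host transcript of a basal epithelial microRNA, 6.95-fold (-2.80 ± 0.34). Anxa8, an annexin, fell by 2.70, and Hr, a nuclear corepressor of skin and hair, by 2.67 on the log2 scale, and the desmosomal plakophilin Pkp1 fell 6-fold (-2.59 ± 0.15). Lypd3 fell 5.86-fold, Perp, a desmosomal tetraspan protein, 5.52-fold, and Duoxa1, the maturation factor of a hydrogen peroxide-producing oxidase, 5.41-fold. Each of the falls named here stayed past the threshold when any array was left out.

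The largest rise was that of Prm1, the sperm protamine, at 3.19 ± 0.14 (9.13-fold, adjusted p = 0.000155). Its probe lies at chromosome 16, 10796450 to 10796509 (mm9), and control RNA was well above background there on 4 arrays. The gasdermin genes Gsdmc3, Gsdmc4 and Gsdmc rose 8.4-fold, 6.16-fold and 6.04-fold (3.07 ± 0.43, 2.62 ± 0.32 and 2.60 ± 0.38). These 3 are close paralogs, and signal shared between their probes was not examined. Msln, the surface glycoprotein mesothelin, rose 7.14-fold (2.84 ± 0.17), and Spp1, the secreted matrix protein osteopontin, 6.14-fold (2.62 ± 0.55). Fabp1, a fatty acid-binding protein of liver and gut, rose 5.56-fold (2.48 ± 0.46) and Cubn, the endocytic receptor cubilin, 4.83-fold (2.27 ± 0.52). Lypd8, an antibacterial protein of the colon epithelium, rose 4.27-fold (2.09 ± 0.45), and the carbonic anhydrase Car2 3.95-fold (1.98 ± 0.31). Phgr1 was at least 3.67-fold higher in the cKO (adjusted p = 0.00599), its control RNA being well above background on 1 of 4 arrays. Fgg, a fibrinogen chain made by hepatocytes, had a ratio of 2.09 ± 1.11 (adjusted p = 0.0458), and its call ended when array 1, 2 or 3 was left out, with adjusted p-values of 0.166, 0.051 and 0.0742. Hepatocyte markers, a list written after the values were seen, had a median of 1.01 ± 0.62 in the same arrays (0.73, 1.76, 1.04 and 0.28). With the members of that list and of an adrenal cortex list taken out of the finished counts, 518 genes were higher and 1023 lower. No new fit was made, and this does not show how many of the remaining genes rose together with the hepatocyte markers.

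Basal urothelial genes formed the group with the deepest fall. Of 30 tested members of the list, 23 fell, 2 rose and 5 did not pass; adjusted over the list alone, 25 fell and 2 rose. The median log2 ratio was -1.18 ± 0.11 (SD over arrays, n = 4), and that of genes shared by most epithelia was -0.45 ± 0.28. Shh, the secreted signal of the ureter epithelium, fell 4.62-fold (-2.21 ± 0.07), and Sox15, a transcription factor, fell 4.71-fold (-2.24 ± 0.10, adjusted p = 0.000233). The members that rose were Cyp2f2, a cytochrome P450, at 1.77 ± 0.25, and the desmocollin Dsc3 at 0.74 ± 0.14. The integrin subunit Itga6 had a ratio of 0.18 ± 0.24 (adjusted p = 0.355) and Cd44 one of -0.20 ± 0.15 (adjusted p = 0.177). With an array left out these ratios ranged from 0.05 to 0.31 and from -0.29 to -0.12. Camera gave an adjusted p of 2.36e-17 with the preset correlation and an adjusted p of 0.316 with an estimated correlation; fry gave an adjusted p of 0.00492.

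Of the uroplakin genes of the superficial urothelium, Upk1a, Upk1b, Upk2 and Upk3a did not pass the test over all genes, and the related Upk3bl fell. Of 27 tested members of the superficial list, 6 fell, 1 rose and 20 did not pass; adjusted over the list alone, 16 fell and 1 rose. Upk1a had a ratio of -0.67 ± 0.45 (adjusted p = 0.0503), Upk1b of -0.63 ± 0.51 (0.117), Upk2 of -0.46 ± 0.29 (0.0878) and Upk3a of -0.22 ± 0.33 (0.385). Adjusted over the list alone, these values were 0.0146, 0.035, 0.0287 and 0.194. Among the members that fell were Upk3bl (-1.90 ± 0.22), the monooxygenase Fmo5 (-1.58 ± 0.35), the retinol dehydrogenase Adh7 (-1.30 ± 0.35) and the keratin Krt7 (-1.22 ± 0.35). The transcriptional cofactor Vgll1 rose (0.90 ± 0.50), a call that ended without array 2 (adjusted p = 0.0806) or array 3 (0.0502). With an array left out, the ratio of Upk1b ranged from -0.88 without array 3 to -0.38 without array 1, and that of Upk3a from -0.36 without array 2 to -0.08 without array 4. The list median was -0.45 ± 0.35 and ranged from -0.86 on array 1 to -0.04 on array 2, and was -0.26 without array 1. Camera gave an adjusted p of 1.12e-05 with the preset correlation, an adjusted p of 0.552 with an estimated correlation, and fry an adjusted p of 0.207.

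Of 34 tested genes shared by most epithelia, 12 fell, 0 rose and 22 did not pass; adjusted over the list alone, 23 fell. The list median was -0.45 ± 0.28, with a camera adjusted p of 9.23e-09, an adjusted p of 0.499 with an estimated correlation, and a fry adjusted p of 0.134. Grhl2, a transcription factor of epithelial junctions, fell 2.34-fold (-1.23 ± 0.38, adjusted p = 0.00791). The tight junction claudin Cldn4 fell 1.75-fold (-0.81 ± 0.25), a call that ended without array 1 (adjusted p = 0.0521), and the serine protease Prss22 had a ratio of -0.65 ± 0.22, with an adjusted p of 0.0721 without array 4. E-cadherin had a ratio of -0.59 ± 0.18 (Cdh1, adjusted p = 0.0179, 0.0827 without array 1 and 0.0597 without array 3). Krt8, a keratin of simple epithelia, had a ratio of 0.00 ± 0.36.

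**Figure D2:**
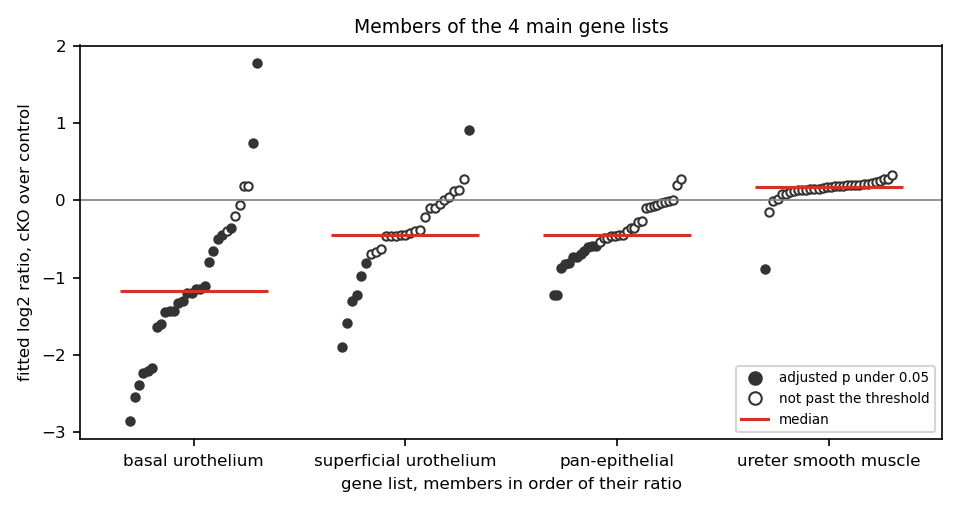
Fitted log2 ratio of cKO over control (vertical axis) of each member of the 4 main gene lists, filled where the adjusted p is under 0.05, with the list median as a red line. The medians are -1.18, -0.45, -0.45 and 0.17.

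Ureter smooth muscle genes lay slightly above 0 as a group, while its members did not pass on their own except Rgs5. Of 32 tested members, 0 rose, 1 fell and 31 did not pass, over all genes and adjusted over the list alone. The median was 0.17 ± 0.08. Camera gave an adjusted p of 5.62e-06, an adjusted p of 0.499 with an estimated correlation, and fry an adjusted p of 0.125. The medians of the endothelial, skeletal muscle, nerve and mesenchyme lists were also above 0 (0.17, 0.18, 0.10 and 0.08), and that of the leukocyte list was -0.07. Whether a lower share of epithelial cells in the cKO raised such medians was not tested. Rgs5, a regulator of G protein signalling in pericytes and smooth muscle, fell 1.86-fold (-0.90 ± 0.23, adjusted p = 0.00698). Smooth muscle actin had a ratio of 0.14 ± 0.14 (Acta2, adjusted p = 0.213) and smooth muscle myosin one of 0.19 ± 0.14 (Myh11, adjusted p = 0.159). In the list of ureter mesenchyme and fibroblasts 1 of 35 tested members rose, and none did adjusted over the list alone. That member, the transcription factor Gata6, had a ratio of 0.42 ± 0.15 (adjusted p = 0.0305), and its call ended without array 1 (0.117), array 2 (0.0552) or array 4 (0.123). Tbx18, which marks the ureteric mesenchyme, had a ratio of 0.17 ± 0.11 (adjusted p = 0.182). The list had a median of 0.08 (0.01 without array 1 and 0.13 without array 3) and an adjusted camera p of 0.0274, of 0.635 without array 1, of 0.136 without array 2, of 0.0636 with Agilent's processed signals and of 0.0604 with the deposited value table, an adjusted p of 0.656 with an estimated correlation, and a fry adjusted p of 0.458.

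In the desmosome and junction list 17 of 29 tested members fell, 1 rose and 11 did not pass, and 19 and 1 adjusted over the list alone, with a median of -0.47 ± 0.17. Beside Pkp1 and Perp, Nectin1, an adherens junction protein, fell 3.06-fold (-1.62 ± 0.20), P-cadherin fell 3.03-fold (Cdh3, -1.60 ± 0.25), and desmoplakin 2.35-fold (Dsp, -1.24 ± 0.35). In the hemidesmosome and basement membrane list 9 of 30 fell, 0 rose and 21 did not pass, and 13 fell and 3 rose adjusted over the list alone, with a median of -0.09. The integrin subunit Itgb4 fell 5.27-fold (-2.40 ± 0.34), Fermt1, an integrin activator, 3.66-fold (-1.87 ± 0.11, with cKO RNA well above background on 3 of 4 arrays), and the laminin chains Lamb3 and Lama3 2.72-fold and 2.36-fold. The mean log2 intensity of Fermt1 in the cKO was 6.71, within the range of the Y-linked probes in female RNAs, so its fold may be too small. Camera gave adjusted p-values of 3.94e-11 and 0.00191 for these lists, an adjusted p of 0.499 for both with an estimated correlation, and fry 0.0454 and 0.0354. In the squamous and cornified list 7 of 20 fell and 2 rose, and 9 and 2 adjusted over the list alone. The protease inhibitor Serpinb5 fell 5.07-fold (-2.34 ± 0.21) and involucrin, a component of the cornified envelope, 4.28-fold (Ivl, -2.10 ± 0.44). Loricrin rose 1.54-fold (Lor, 0.62 ± 0.06), and Krt4 had a ratio of 1.13 ± 0.39, with an adjusted p of 0.0151 and of 0.0628 without array 4. Camera gave this list an adjusted p of 6.03e-05, an adjusted p of 0.316 with an estimated correlation, and fry an adjusted p of 0.00492.

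**Figure D3:**
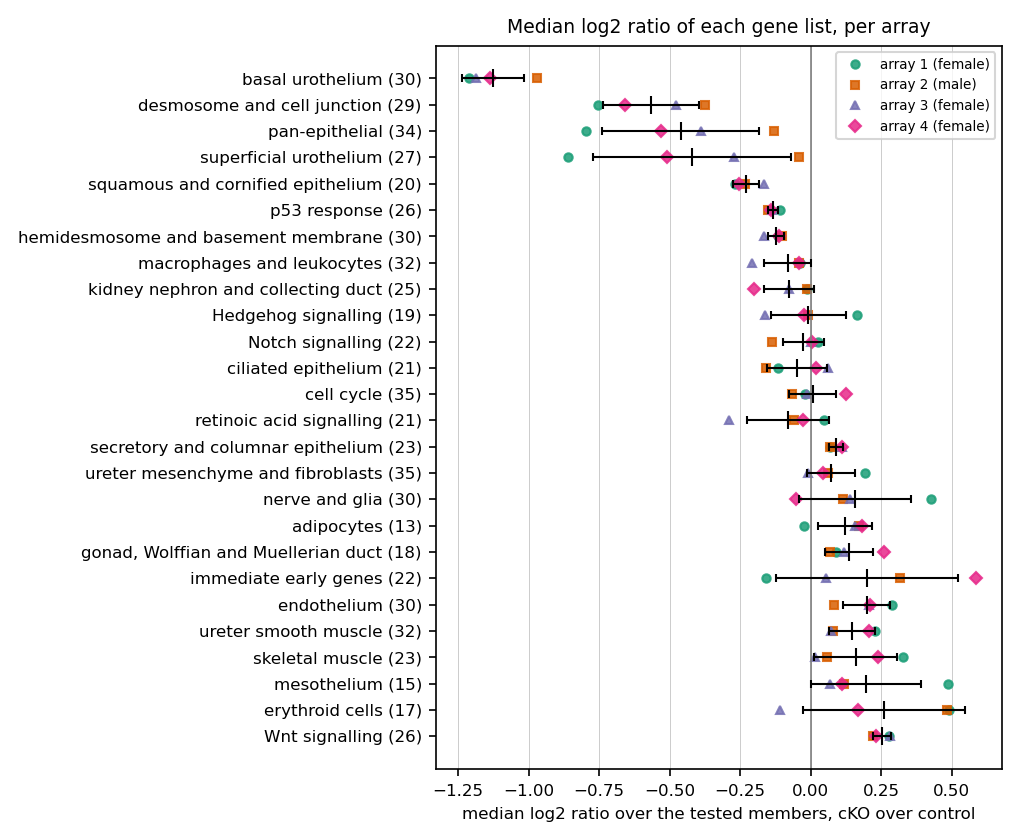
Median log2 ratio of cKO over control (horizontal axis) over the tested members of each of the 26 gene lists, with the number of members in brackets, a symbol per array, and bars for the mean and SD of 4 arrays. Basal urothelium is lowest at a median of -1.18 over the fitted ratios, and Wnt signalling is highest at 0.29.

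In the ciliated list 7 of 21 fell and 0 rose, over all genes and adjusted over the list alone; the axonemal dynein chain Dnaic1 fell 2.55-fold (-1.35 ± 0.08), Ccdc113 2.34-fold (-1.23 ± 0.19), Cfap43 1.66-fold (-0.74 ± 0.17) and Cfap52 1.56-fold (-0.64 ± 0.05). The list median was -0.01 and its mean -0.23, and the median was 0.03 without array 1, 0.02 without array 2, -0.05 without array 3 and -0.08 without array 4. Camera gave an adjusted p of 0.0402, which was 0.168 without array 1, 0.138 without array 2, 0.0517 with scaling between arrays and 0.0561 with the mean of all probes, an adjusted p of 0.499 with an estimated correlation, and fry gave an adjusted p of 0.0454. In the secretory and columnar list 4 of 23 rose and 4 fell, over all genes and adjusted over the list alone, and camera gave an adjusted p of 0.329, an adjusted p of 0.588 with an estimated correlation, and fry one of 0.516. The secreted proteins Bpifb1 and Wfdc2 fell 2.85-fold and 2.04-fold (-1.51 ± 0.31 and -1.03 ± 0.18), and Agr3, a disulfide isomerase, fell 1.73-fold with cKO RNA well above background on 3 of 4 arrays. Clca2, a chloride channel regulator, was not well above background in the cKO on any array and was at least 1.29-fold lower there (adjusted p = 0.0133). The mucin Muc20 had a ratio of 0.89 ± 0.43 (adjusted p = 0.0175, and 0.0724 without array 4), and the Wnt target gene Lgr5 one of 0.58 ± 0.23 (adjusted p = 0.0269, 0.0743 without array 2 and 0.0878 without array 3). The trefoil factor Tff3 had a ratio of 0.99 ± 0.39 (adjusted p = 0.0144, and 0.0516 without array 3), and its control RNA was well above background on 3 of 4 arrays.

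Of 26 tested Wnt signalling members 11 rose, 2 fell and 13 did not pass, and 17 rose and 2 fell adjusted over the list alone, with a median of 0.29 ± 0.03. Camera gave an adjusted p of 1.44e-05, an adjusted p of 0.316 with an estimated correlation, and fry an adjusted p of 0.0454. The ligands Wnt10a and Wnt6 fell 4.39-fold and 2.43-fold (-2.13 ± 0.14 and -1.28 ± 0.21), and the ligand Wnt9b rose 2.45-fold (1.29 ± 0.35). The Wnt target genes Axin2 and Sp5 rose 1.72-fold and 1.69-fold (0.78 ± 0.30 and 0.76 ± 0.25). Of 22 Notch members 4 fell and 0 rose, and 5 and 1 adjusted over the list alone. The ligand Jag2, the Notch regulator Nrarp and the Notch target Hes1 fell 2.16-fold, 2.17-fold and 2.02-fold, and Jag1 had a ratio of -0.45 ± 0.15, with an adjusted p of 0.0181, of 0.0711 without array 1, of 0.053 without array 2 and of 0.0786 without array 3. Of 21 retinoic acid members 7 fell and 2 rose, and 9 and 6 adjusted over the list alone. The aldehyde dehydrogenases Aldh1a7 and Aldh1a1 fell 4.76-fold and 2.34-fold (-2.25 ± 0.23 and -1.23 ± 0.08). The members that rose were the retinoic acid-degrading enzyme Cyp26a1 (at least 1.34-fold), whose control RNA was well above background on 1 of 4 arrays, and the retinol transporter Stra6 (0.94 ± 0.48). The Cyp26a1 call ended without array 1 (0.0606) or array 4 (0.066), and the Stra6 call without array 2 (0.0638) or array 4 (0.108). Of 19 Hedgehog members 2 fell, over all genes and adjusted over the list alone. Beside Shh this was its receptor Ptch1, at -0.53 ± 0.24, while the members Gli1 and Hhip had ratios of -0.11 ± 0.20 and -0.07 ± 0.11 (adjusted p = 0.523 and 0.58). Camera gave adjusted p-values of 0.329 for Notch, 0.356 for retinoic acid and 0.599 for Hedgehog genes, with adjusted p-values of 0.739, 0.739 and 0.891 with an estimated correlation and of 0.154, 0.119 and 0.153 with fry. The median of the retinoic acid genes was 0.03 (-0.10 without array 1 and 0.16 without array 3) and their mean -0.19.

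Of 35 cell cycle genes 0 passed the limma test, over all genes or adjusted over the list alone, and 1 was higher and 1 lower at an unadjusted p under 0.05. Their median was 0.01 (0.07 without array 2 and -0.04 without array 4); Ccna2 and Pcna had ratios of 0.01 ± 0.14 and 0.01 ± 0.15. The camera adjusted p of the list was 0.527 and that of fry 0.854, and the camera value was 0.0172 without array 2. Of 26 genes of the p53 response 6 fell and 0 rose, and 11 and 2 adjusted over the list alone. Their median was -0.14 ± 0.02. Beside Perp, Phlda3, a repressor of Akt signalling, fell 1.45-fold (-0.54 ± 0.17), and Ccng1 had a ratio of -0.39 ± 0.08 (adjusted p = 0.0162, 0.0713 without array 1, 0.0742 without array 3 and 0.0751 without array 4). Sesn2, a stress-induced sestrin, had a ratio of -0.34 ± 0.06, and its call ended with any array left out (adjusted p from 0.0585 without array 2 to 0.101 without array 4). The list had an adjusted camera p of 0.000267, an adjusted p of 0.316 with an estimated correlation, and a fry adjusted p of 0.0143. Among 22 immediate early genes, which respond to handling, 1 fell and 1 rose, and 1 and 3 adjusted over the list alone. The phosphatase gene Dusp2 fell 2.02-fold (-1.02 ± 0.18), and Nr4a1 had a ratio of 0.55 ± 0.58 (adjusted p = 0.0364, 0.0974 without array 1, 0.128 without array 3 and 0.0715 without array 4). The Nr4a1 ratios on arrays 1 to 4 were -0.01, 0.74, 0.19 and 1.28, so the sign was not the same on each array. The median of this list was 0.16 ± 0.32, from -0.16 on array 1 to 0.59 on array 4, and was 0.28 without array 1, 0.29 without array 2, 0.10 without array 3 and 0.10 without array 4. Its adjusted camera p of 0.00613 was 0.152 without array 3, 0.123 without array 4 and 0.0807 with a trended and robust variance, with an adjusted p of 0.582 with an estimated correlation and of 0.473 with fry.

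Of 32 leukocyte genes 3 fell and 0 rose, over all genes and adjusted over the list alone, and these were mast cell proteases. Cpa3 fell 1.99-fold (-0.99 ± 0.08), Cma1 1.81-fold (-0.86 ± 0.06), and Mcpt4 had a ratio of -0.45 ± 0.14, with an adjusted p of 0.0234, of 0.103 without array 1, of 0.0695 without array 2 and of 0.0575 without array 3. Of 30 endothelial genes 3 rose and 0 fell, and 8 and 0 adjusted over the list alone, with a median of 0.17 ± 0.08. The lymphatic endothelial gene Mmrn1 rose 1.86-fold (0.89 ± 0.17). The transcription factors Tal1 and Sox17 had ratios of 0.26 ± 0.05 and 0.41 ± 0.19. The Tal1 call ended with any array left out (adjusted p from 0.0992 without array 2 to 0.196 without array 4), and the Sox17 call without array 1 (0.194), array 3 (0.112) or array 4 (0.134). Of 30 nerve and glia genes 4 rose and 2 fell, and 8 and 2 adjusted over the list alone; Uchl1, a deubiquitinase of neurons, fell 2.04-fold (-1.03 ± 0.29), and the synaptic gene Syt1 had a ratio of 0.73 ± 0.26, with an adjusted p of 0.0143 and of 0.0597 without array 4. Phox2a, a transcription factor of autonomic neurons, had a ratio of 0.52 ± 0.36 (adjusted p = 0.0189, 0.0866 without array 1 and 0.0527 without array 3). Camera gave adjusted p-values of 0.00931, 9.95e-09 and 0.0176 for leukocyte, endothelial and nerve genes, and an adjusted p of 0.499 for each with an estimated correlation, and fry gave adjusted p-values of 0.0913, 0.0664 and 0.291. The leukocyte call ended without array 3 (0.181) or in separate channels without a block (0.0726), and the nerve call without array 1 (0.0554) or array 2 (0.138). The leukocyte median of -0.07 was -0.10 without array 1 and -0.01 without array 3. The nerve median of 0.10 was 0.04 without array 1 or array 2, 0.19 without array 3 and 0.16 without array 4.

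Of 25 kidney genes 4 rose and 2 fell, over all genes and adjusted over the list alone, with a camera adjusted p of 0.805, an adjusted p of 0.891 with an estimated correlation, and a fry adjusted p of 0.673. The median was -0.05 (-0.13 without array 2, -0.02 without array 3 and 0.05 without array 4) and the mean 0.09. Beside Cubn, the sodium channel subunit Scnn1b rose 2.56-fold (1.36 ± 0.24) and the vasopressin receptor Avpr2 1.54-fold (0.62 ± 0.20). The receptor Ret had a ratio of 0.57 ± 0.22 (adjusted p = 0.022, 0.0755 without array 2 and 0.074 without array 4), and the transcription factor Emx2 one of -0.62 ± 0.23 (adjusted p = 0.0165, 0.0771 without array 1 and 0.0553 without array 3). Of 15 mesothelial genes 2 rose and 1 fell, over all genes and adjusted over the list alone. These were Msln and Dmkn, at 0.60 ± 0.16, and Ezr, at -0.53 ± 0.28, whose call ended without array 1 (adjusted p = 0.121), array 2 (0.0664) or array 4 (0.163). The mesothelial list had an adjusted camera p of 0.0763, and of 0.0099 without array 3, and an adjusted fry p of 0.0613. Of 18 gonad and duct genes 3 rose, and 4 adjusted over the list alone. Hsd3b1, a steroid dehydrogenase, had a ratio of 1.84 ± 0.73, with an adjusted p of 0.0206 and of 0.0635 without array 1. The homeobox gene Hoxd13 and the paired box gene Pax8 had ratios of 0.51 ± 0.26 and 0.44 ± 0.25. The Hoxd13 call ended without array 1 (0.168), array 3 (0.137) or array 4 (0.0703), and the Pax8 call without array 2 (0.13), array 3 (0.0924) or array 4 (0.153). Camera gave this list an adjusted p of 0.00156, and an adjusted p of 0.345 with an estimated correlation, and fry an adjusted p of 0.0143.

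Of 17 erythroid genes 1 rose and none did adjusted over the list alone, with a median of 0.26 ± 0.29, which was 0.11 without array 1 and 0.43 without array 3. That gene, Hbb-b2, had a ratio of 0.40 ± 0.16 (adjusted p = 0.0431, 0.173 without array 1, 0.101 without array 2 and 0.103 without array 3). Of 13 adipocyte genes 3 rose and 0 fell, and 3 and 1 adjusted over the list alone; the carbonic anhydrase Car3 rose 1.79-fold (0.84 ± 0.18) and the glycerol phosphate dehydrogenase Gpd1 1.97-fold (0.98 ± 0.34). Cidea, a lipid droplet protein, had a ratio of 0.44 ± 0.19 (adjusted p = 0.0278, 0.0844 without array 2, 0.0732 without array 3 and 0.109 without array 4). Of 23 skeletal muscle genes 2 rose and 0 fell, and 3 and 1 adjusted over the list alone. These were Actn3 at 0.39 ± 0.10 and Tnnt1 at 0.27 ± 0.12, with adjusted p-values of 0.107 and 0.207 without array 1. The Actn3 call also ended without array 3 (0.0645) or array 4 (0.0985), and the Tnnt1 call without array 2 (0.117), array 3 (0.0983) or array 4 (0.195). Camera gave adjusted p-values of 0.000337, 0.0367 and 0.0048 for the erythroid, adipocyte and skeletal muscle lists, and adjusted p-values of 0.552, 0.499 and 0.552 with an estimated correlation. Fry gave 0.317, 0.0916 and 0.294. The skeletal muscle median of 0.18 was 0.01 without array 1 and 0.12 without array 4. The adipocyte call ended without array 2 (0.0594) or array 3 (0.181) or with Agilent's processed signals (0.0636), and the skeletal muscle call without array 1 (0.146) or array 4 (0.0897).

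The ratio of cKO over control in the male pair was compared with that in the female pairs. With the dye as a term the fitted difference is that between array 2 and array 4, which share a dye orientation, and 1 residual degree of freedom is left. The limma test gave 0 genes higher and 0 lower, but this count says little about whether the sexes were alike. Even Xist, with a fitted difference of 2.20, had an adjusted p of 0.18. Of 18161 genes, 861 had an unadjusted p under 0.05, and 0 passed with a trended and robust variance or with no filter. The lowest p belonged to Trf, transferrin, with a ratio of 1.00 on array 2, the male pair, and of -1.91 on array 4, a fitted difference of 2.91 (adjusted p 0.18). Other genes made by hepatocytes, such as Kng2 and Serpinc1, had fitted differences of 3.27 and 2.03. The hepatocyte list had a median of 1.76 in the male pair and of 0.73, 1.04 and 0.28 in the female pairs. Large differences were not limited to hepatocyte markers: Lrp2 and Slc34a1 of the kidney list had fitted differences of 1.99 and 1.73. The median of the whole kidney list was -0.01 on array 2 and -0.20 on array 4. The lone male pair was assumed to vary like the others.

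The sex labels were checked with Xist, which is transcribed from the inactive X chromosome, and with 4 Y-linked genes. Ddx3y had normalized log2 intensities of 13.68 in the cKO and 13.75 in the control of array 2, against a mean of 6.34 ± 0.25 (SD, n = 6) in the female RNAs. Eif2s3y, Kdm5d and Uty were likewise high only in the RNAs of array 2. The Xist probe at X, 100662174 to 100662233 (mm9), had a mean of 12.59 ± 0.25 in the female RNAs, 9.54 in the male cKO and 7.58 in the male control. At the Xist probe from 100656289 to 100656348 the corresponding values were 11.86 ± 0.42, 9.14 and 6.28. In the male cKO the Xist signal was thus up to 12.1% and 15.1% of the female mean at these probes, since the intensities include the offset of 50. In the male control it was up to 3.09% at the former probe and not well above background at the latter. Whether the male cKO RNA held some female RNA was not settled by these values, which limits the comparison of the male pair with the female pairs.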

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

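The tests of epithelial share, germ cells, transgene, liver RNA and a uniform genotype effect were chosen after the results were seen; the test of other assignments of genotype to channels was planned. Over 131 quantities tested with 4 arrays each, 16 had an array apart from the others, where chance gives about 6.55.

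Several genes and gene lists had 1 array apart from the other 3. Mir205hg had a log2 ratio of -2.29 on array 2 and of -2.94 or lower on the others. Lama3 had a ratio of -1.36 on array 3, Clca2 of -0.52 on array 2 and Aldh1a1 of -1.11 on array 1. Tal1 had a ratio of 0.34 on array 4, Cidea of 0.73 on array 3 and Pax8 of 0.82 on array 3. The median ratio of the Notch list was -0.13 on array 2, that of the leukocyte list -0.21 on array 3, that of the adipocyte list -0.0229 on array 1 and that of the mesothelial list 0.49 on array 1.

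On array 1, 90.0% of green spots and 82.6% of red spots were well above background, more than on the other arrays, and the median red signal was 550.77 units, less than on the others. The Xist ratio of cKO over control was 2.86 and 1.97 at its 2 probes on array 2, the male pair, against -0.33 to 0.08 and -0.23 to -0.14 on the female pairs. Of 3130 tested probes without a gene name, 39 passed the limma threshold, 8 higher and 31 lower in the cKO.

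Basal genes fell more than the genes shared by most epithelia, and a lower share of epithelial cells in the cKO could lower both. As the sole cause of the basal falls, a lower share would lower both lists alike if their members were expressed in epithelial cells alone. The basal median without Trp63 lay below the pan-epithelial median by a mean of -0.62 ± 0.19 on the log2 scale (-0.38, -0.75, -0.78 and -0.58 on arrays 1 to 4). As the sole cause of the pan-epithelial falls, a lower share would give 1 common fall on each array under the same condition, with probes that respond alike. Neither condition was tested, so the next test cannot exclude a lower share as the sole cause of the pan-epithelial falls. The 34 members' ratios less the list median of the array differed from 0 by limma's rotation test (roast), which keeps the correlation between members, at an adjusted p of 0.0218. This form was chosen after a count that took the members as independent was set aside; other set statistics gave adjusted p-values of 0.0123 to 0.0136 and fry gave 0.00597. With an array left out the adjusted p was 0.043 to 0.119 and passed only without array 1, so the margin is small. A lower share stays open, alone or beside changes in single genes, as does a change of epithelial genes by the loss of ΔNp63, which the design names. Whether basal genes fell per cell or with the number of basal cells was not tested.

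Prm1 was higher on each array, the lowest ratio being 2.99. RNA of male germ cells would bring the other spermatid transcripts, but the highest ratio of Prm2, Prm3, Tnp1 or Tnp2 on any array was 0.12. Prm1 sequence carried by the cre transgene, present only in the cKO per the labels, may account for a signal of this kind; this is a hypothesis, since the sequence of the construct was not used here. A rise of the endogenous gene in the cKO was not separated from it.

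Hepatocyte markers were higher in the cKO by a median of 1.01, with 35 of 37 tested members above 0 on average and 26 above 0 on 4 arrays. Of the 37, 2 belong to another of the 26 planned lists, and 35 were also well above background in the control. Fabp1 is also a member of the intestinal list. By limma 10 rose, and 23 adjusted over the list alone. Camera gave an adjusted p of 2.38e-13 with the preset correlation and of 0.332 with an estimated correlation, and fry gave an adjusted p of 0.108. A genotype effect of 1 size would give like medians, but they lay 1.48 apart over the arrays. Liver RNA carried over in differing amounts could give the SD of 0.62, which was above those of the 4 main lists (0.11, 0.35, 0.28 and 0.08). The abundant liver transcripts Apoa2, Apoc3 and Ttr had ratios of 0.43 ± 0.28, 0.03 ± 0.03 and 0.71 ± 0.47 beside 1.68 ± 0.99 for Alb. Other liver transcripts rose like Alb: Apoa1 by 1.55 ± 0.83, Ahsg by 1.77 ± 0.85 and Fgb by 1.71 ± 0.91. The Apoc3 probe was dim, at mean log2 intensities of 8.04 in the cKO and 8.01 in the control, so its ratio says little. Carried-over liver RNA and a genotype effect that differs between genes and embryos cannot be told apart here, since each array holds 1 RNA of each genotype.

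With cKO and control exchanged on some of the arrays, 7 assignments were open to a fit beside the dye term, and 1 of them, the real one, gave as many genes past the threshold. The real count was 1553 and the highest of the others 0. The assignments are too few for a share under 0.05. In the other assignments, differences between the genotypes enter the residual spread, which by itself lowers the counts. The contrast of 1553 with 0 is therefore no separate support.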

How the results depend on the processing

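The count without hepatocyte and adrenal cortex members was chosen after the data were seen; the other alternatives were planned, and a slide or scan block was not run, since all arrays share 1 slide and scan. No call of a named gene or gene list turned to the opposite direction, by the ratio of the gene or the camera direction of the list; the medians of the ciliated, Hedgehog, retinoic acid, Notch, cell cycle and kidney lists, close to 0, changed sign under at least 1 alternative. The 1553 genes past the threshold had the same sign without background subtraction, with Agilent's processed signals, with median centring, with scaling, without the dye term and with each array left out, though fewer passed with an array left out; 1552 had it with no filter and with the mean of all probes, and 1479 with a strict filter and 1516 with the deposited value table, where fewer genes were tested. Genes higher in the cKO numbered 530, against 37 without the array as a block and 1472 with it in fits of separate channels, 977 at an adjusted p under 0.1, 185 at a fold of at least 1.5, and 277 to 359 with an array left out. Genes lower numbered 1023, against 193, 1899, 514 with the fold rule and 554 to 768 with an array left out; the main ratio model is itself paired, and 3 arrays leave fewer degrees of freedom. By size alone 89 and 201 genes passed, against 166 and 307 with Agilent's processed signals, and the cause was not tested. With an estimated correlation, which rests on 2 residual degrees of freedom, camera gave adjusted p-values of 0.316 for the basal, 0.552 for the superficial, 0.499 for the pan-epithelial and 0.499 for the smooth muscle list. Fry gave 0.207 for the superficial, 0.134 for the pan-epithelial and 0.125 for the smooth muscle list. Over the gene lists and the alternatives that kept all arrays, 381 results kept their side of the threshold and 37 were weaker; with an array left out, 89 kept it, 13 were weaker and 2 stronger. Over the named and further marker genes, 1915 kept it, 132 were weaker and 29 stronger, and with an array left out 473, 115 and 8. Between 72.4% and 90.0% of spots per channel were well above background, and genes below it were not tested.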

Other observations

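The lists of intestinal epithelium and adrenal cortex genes were written after the data were seen. Intestinal genes went both ways in the cKO ureters: of 18 tested members 5 rose and 3 fell, and 6 and 4 adjusted over the list alone. Fabp1 and Lypd8 were among the largest rises. The galectins Lgals4 and Lgals6 had ratios of 1.05 ± 0.63 and 1.35 ± 0.69 (SD, n = 4), with limma adjusted p-values of 0.0429 and 0.0321; without array 2 these were 0.12 and 0.0913, and without array 4 0.117 and 0.107. The antibacterial lectin Reg3g fell 2.31-fold (-1.21 ± 0.32, adjusted p = 0.00275) and the intestinal peptide hormone gene Guca2a 2.05-fold (-1.04 ± 0.20). Reg3g was dim in the cKO, at a mean log2 intensity of 6.92. The median of the intestinal list was 0.03, with a camera adjusted p of 0.183, an adjusted p of 0.57 with an estimated correlation, and a fry adjusted p of 0.108.

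Of 11 tested adrenal cortex genes 2 rose and 0 fell, and 4 and 0 adjusted over the list alone; 6 were higher and 0 lower at an unadjusted p under 0.05. Beside Hsd3b1, the steroid hydroxylase Cyp11b1 was at least 1.88-fold higher (limma adjusted p = 0.0228, and 0.0825 without array 4), and its control RNA was well above background on 1 of 4 arrays. The list median was 0.18 ± 0.16, with a camera adjusted p of 0.000989, an adjusted p of 0.332 with an estimated correlation, and a fry adjusted p of 0.108.

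Among hepatocyte genes, the cytochrome P450 Cyp2e1 rose 2.92-fold (1.55 ± 0.25, adjusted p = 0.00057) and varied less between arrays than Afp, the fetal serum protein, at 1.93 ± 0.98 (adjusted p = 0.0384). The Afp call ended without array 1 (0.134), array 2 (0.055) or array 3 (0.0544).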
